A study of Homo sapiens with 18 samples.

How the data were processed

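RNA was measured in 18 libraries of the breast cancer cell line MCF-7 with the empty vector LXSN, wild-type PELP1 or cytoplasmic PELP1, 3 per group. Per the labels, cells were starved for 16 h in medium with 5% charcoal-stripped serum and treated for 6 h with ethanol or 1 nM estradiol. Libraries were made with TruSeq RNA v2, which does not record the strand, and read on a HiSeq instrument. The submitters' processing notes name FastQC 0.11.2, TopHat2 2.0.13, Cufflinks 2.2.1 and the genome build hg19. The deposited table holds FPKM (fragments scaled by transcript length and library size), made by the authors and already rescaled between libraries. The file states no unit, so FPKM was read from the tools named and from the values: they are fractional, and columns sum to between 663194 and 1.21871e+06. Genes of small RNAs held 22.3 to 56.8% of these sums, so sums were not used as depth. The annotation, the filters and the scaling method of the authors are not stated in the labels.

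Depth is not given as counts. In each pair of libraries, genes seen in only 2 to 8 libraries took ratios that cluster at small whole ratios, since each holds few fragments, and the common factor of these ratios gave a depth relative to the deepest library. Between 80.9 and 94.6% of the ratios lay at such steps (log2 tolerance 0.02, at least 92 genes per pair). This sets a scale between libraries only: no counting interval can be given.

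The table lists 23604 genes by symbol. Of these, 22657 matched a symbol or older symbol in the reference table of gene names (12112 of the 12376 tested), and 28 were turned into dates by spreadsheet software (19 tested) and never named. Of the tested genes 93 were listed at 0 in some library. In 27 the other libraries exceeded 20 FPKM, and 26 of those were small RNA genes, for which Cufflinks values are erratic. The reference annotation uses another build, so no coordinates are given.

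Genes with at least 1 FPKM in at least 3 libraries were kept. Values were analysed as log2(FPKM + 1) in limma 3.58.1 under R 4.3.3 (lmFit, contrasts.fit, eBayes with a trend, prior degrees of freedom 4.56), with 1 mean per group over all 18 libraries. Tests were two-sided, with Benjamini-Hochberg adjustment over the tested genes within each comparison and a threshold of adjusted p 0.05. The 12 comparisons were E2 against vehicle in each of the 3 lines, the 3 pairs of lines within each treatment, and 3 interactions that ask whether the E2 response differs between lines. An exact permutation test of 3 libraries against 3 cannot go below p = 0.1, so such tests were not used for single genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for depth and figures.

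Gene lists, 30 in number and 28 with a tested gene, were written before the values were read. They cover classical E2-induced genes, E2-repressed genes, breast cancer stem cell markers, glycolysis, hypoxia response, PELP1 and AIB1 complex genes, 5FMC and Rix1 complex genes, ribosome biogenesis, G1/S and replication, G2/M and mitosis, MYC and immediate-early genes, interferon-stimulated genes, NF-kB and inflammatory genes, antigen presentation, EMT and mesenchymal genes, luminal epithelial genes and basal epithelial genes. They also cover progesterone receptor-associated genes, cholesterol biosynthesis, oxidative phosphorylation, unfolded protein and amino-acid stress, p53 targets, apoptosis regulators, growth factor receptor signalling, markers of fibroblasts, leukocytes, endothelium and basal B breast lines, and mitochondrial transcripts and replication-dependent histones as checks of RNA quality. Each list was tested with camera in limma at a preset correlation of 0.01, adjusted over the lists of a comparison. Counts of called members adjusted over the list alone are given where they differ from those over all tested genes and were equal elsewhere. The estimated correlation between genes of a list (median 0.0464) was used beside it, as was fry, which asks whether a list's genes move one way on balance without comparing them with other genes.

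The naming rule, fixed beforehand, was adjusted p under 0.05. Comparisons of groups also needed no overlap of libraries and a mean of at least 1 FPKM in the higher group. Up to 10 genes per direction with the largest fold change were taken for each comparison of groups (not all are named) and up to 6 for each interaction, with symbols other than those of uncharacterised, small RNA or read-through genes. Up to 4 members with the smallest adjusted p were taken for each described list, and PELP1, NCOA3, ESR1, PGR, PFKFB3 and PFKFB4 were always reported. EMC10's overlapping neighbour FAM71E1 was chosen after its values were seen. GREB1 and MYC are repeated in all lines for comparison.

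The method was tested on simulated data with the spread of these libraries, 200 changed genes among 12376 and 5 data sets per comparison. For E2 in LXSN, 68.4, 92.8, 98.8 and 99.2% of genes changed 1.25-, 1.5-, 2- and 4-fold were recovered, and 4.86% of calls were false. For WT PELP1 against LXSN with vehicle the shares were 66.0, 92.0, 99.2 and 99.6%, with 4.16% false. For the interaction of cyto against WT PELP1 they were 36.8, 78.0, 96.8 and 99.6%, with 5.23% false.

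The alternatives were a pseudocount of 0.1, no filter, quantile normalization, median-ratio scaling, the groups of each comparison fitted alone, replicate number as a block, and each library left out in turn. Robust moderation of the spread and the counts of list members under each setting were added after the data were seen. Overlaps of calls against the same LXSN libraries were set beside 100 simulations of unchanged groups. Left out were genes of the sex chromosomes that the rule on human samples excludes, and genes under the filter.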

Results

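Transcript levels were measured by RNA sequencing in MCF-7, an established breast cancer cell line that carries the estrogen receptor ESR1. Cells carried the empty retroviral vector LXSN, wild-type PELP1 (WT PELP1) or a cytoplasmic form of PELP1 (cyto PELP1). PELP1 is a scaffold protein that binds steroid receptors. Each of the 3 cell lines was starved of hormone and treated with ethanol (vehicle) or estradiol (E2), which gave 6 groups of 3 libraries. The table holds FPKM for 23604 genes, of which 12376 passed the filter on low values and were tested, and 4579 were listed at 0 in every library. Relative to the deepest library, depth averaged 0.950 (range 0.913 to 1) in WT PELP1, 0.866 (0.763 to 0.934) in LXSN and 0.669 (0.624 to 0.711) in cyto PELP1. These ratios were read from steps in the values of low genes, so low genes were measured least precisely in cyto PELP1, and the absolute depth is unknown. Correlations across genes between libraries of one group lay between 0.977 and 0.992. The first principal component held 38.5% of the variance, the second 10.9% and the third 8.97%. LXSN vehicle replicate 1 lay at 6.69 on the second component, against 23.0 and 22.6 for the other LXSN vehicle libraries. All fold changes below are differences of group means on the log2(FPKM + 1) scale, which understates changes of low genes. Errors after ± are SD over 3 libraries, and the error of a fold change is its standard error (SE). The p-values measure only the spread between these samples, since the labels do not say whether the replicates were separate cultures. Called genes named below had no overlap between the compared groups, unless from a list, an interaction or the fixed set of 6 genes.

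The level of the introduced gene was compared first, because it checks the labels. PELP1 stood at 5.71 ± 0.597 FPKM in LXSN, 258 ± 6.61 in WT PELP1 and 237 ± 6.97 in cyto PELP1 with vehicle. With E2 the levels were 9.39 ± 0.547, 168 ± 7.50 and 158 ± 8.06 FPKM. The log2 fold change against LXSN was 5.27 in WT PELP1 and 5.15 in cyto PELP1 with vehicle (adjusted p = 8.53e-20 and 1.24e-19), and 4.03 and 3.93 with E2 (adjusted p = 7.32e-18 and 1.08e-17). Cyto and WT PELP1 were not called different in PELP1 level, with log2 fold changes of -0.12 in vehicle (SE 0.06, adjusted p = 0.169) and -0.09 in E2 (SE 0.06, adjusted p = 0.275). The vehicle difference was called when only the 6 libraries of that comparison were fitted (log2 fold change -0.12, adjusted p = 0.0334). E2 raised PELP1 in LXSN by 0.63 (adjusted p = 5.75e-08) and lowered it in both PELP1 lines, with log2 fold changes of -0.61 in WT PELP1 (adjusted p = 9.25e-08) and -0.59 in cyto PELP1 (adjusted p = 1.91e-07).

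**Figure D1:**
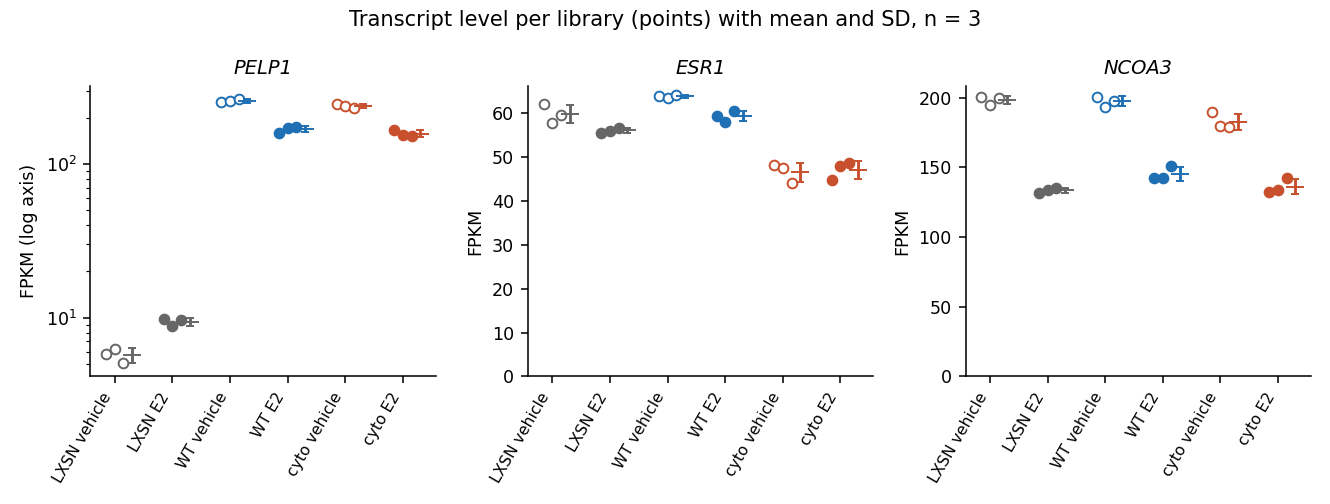
FPKM of PELP1 (log axis), ESR1 and NCOA3 per library (points; open, vehicle; filled, E2) with mean and SD of 3 libraries, by cell line and treatment. PELP1 means range from 5.71 FPKM in LXSN vehicle to 258 FPKM in WT PELP1 vehicle, and the 6 cyto PELP1 libraries lie lowest for ESR1.

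The remaining genes of the fixed set included ESR1 and the coactivator NCOA3 (AIB1), a partner of PELP1 in the study's title. ESR1 with vehicle stood at 59.8 ± 2.12 FPKM in LXSN, 63.8 ± 0.326 in WT PELP1 and 46.5 ± 2.14 in cyto PELP1. In cyto PELP1 it was lower than in LXSN with vehicle (log2 fold change -0.36, adjusted p = 3.08e-06) and with E2 (-0.25, adjusted p = 0.000123). Against WT PELP1 the ESR1 difference was -0.45 with vehicle (adjusted p = 2.55e-07) and -0.33 with E2 (adjusted p = 1.23e-05). WT PELP1 and LXSN were not called different in ESR1 (adjusted p = 0.0688 with vehicle and 0.137 with E2). It was called higher in WT PELP1 with vehicle without LXSN vehicle replicate 1 (log2 fold change 0.12, adjusted p = 0.0387) and with E2 after quantile normalization (0.11, adjusted p = 0.0474). The effect of E2 on ESR1 was -0.09 in LXSN (adjusted p = 0.0469), -0.11 in WT PELP1 (adjusted p = 0.0225) and 0.02 in cyto PELP1 (adjusted p = 0.725). The LXSN call ended with no filter (adjusted p = 0.057), with robust moderation (0.0507), without LXSN vehicle replicate 1 (adjusted p = 0.192) or 3 (0.0831) or without LXSN E2 replicate 1 (0.111), 2 (0.0963) or 3 (0.0654). The WT PELP1 call ended without WT PELP1 vehicle replicate 3 (adjusted p = 0.0579) or WT PELP1 E2 replicate 2 (0.0807).

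NCOA3 fell with E2 from 198 ± 3.01 to 134 ± 1.73 FPKM in LXSN (log2 fold change -0.57, adjusted p = 1.47e-10). It also fell in WT PELP1 (-0.44, adjusted p = 3.62e-09) and in cyto PELP1 (-0.42, adjusted p = 8.85e-09). Between lines NCOA3 differed by at most 0.12 in size. Its log2 fold change with vehicle was -0.01 for WT PELP1 against LXSN (adjusted p = 0.894), -0.12 for cyto PELP1 against LXSN (0.0109) and -0.11 for cyto against WT PELP1 (0.0199). With E2 the values were 0.12 (0.0106), 0.03 (0.578) and -0.09 (0.0534). Several NCOA3 calls rested on single libraries. Cyto PELP1 against LXSN with vehicle ended without cyto PELP1 vehicle replicate 3 (adjusted p = 0.0501), and WT PELP1 against LXSN with E2 ended without WT PELP1 E2 replicate 3 (0.0609). Cyto against WT PELP1 with vehicle ended without WT PELP1 vehicle replicate 1 (0.0735) or 3 (0.0567), without cyto PELP1 vehicle replicate 2 (0.0763) or 3 (0.0845) and after quantile normalization (0.189). Cyto against WT PELP1 with E2 passed without cyto PELP1 E2 replicate 3 (log2 fold change -0.12, adjusted p = 0.0144).

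PFKFB3, an enzyme that speeds glycolysis, rose with E2 from 7.60 ± 0.634 to 17.2 ± 0.0953 FPKM in LXSN (log2 fold change 1.08, adjusted p = 8.62e-12), by 1.04 in WT PELP1 (adjusted p = 1.23e-11) and by 0.99 in cyto PELP1 (adjusted p = 3.57e-11). With vehicle PFKFB3 was 0.15 higher in cyto PELP1 than in LXSN (adjusted p = 0.0272). That call ended without LXSN vehicle replicate 1 (0.0513) or 3 (0.159), without cyto PELP1 vehicle replicate 1 (0.0577) or 2 (0.09) and when only the compared groups were fitted (0.127). The other line differences of PFKFB3 were not called (adjusted p = 0.284 and 0.28 with vehicle, 0.691, 0.356 and 0.698 with E2). The related PFKFB4 stood at 3.87 ± 0.208 FPKM in LXSN vehicle and was called in none of the 9 comparisons of group pairs. Its adjusted p was 0.144, 0.795 and 0.266 for E2 in LXSN, WT PELP1 and cyto PELP1, and 0.381, 0.12 and 0.564 between lines with vehicle and 0.581, 0.523 and 0.969 with E2. Without cyto PELP1 vehicle replicate 1 it was called for E2 in cyto PELP1 (log2 fold change -0.23, adjusted p = 0.0400) and for cyto PELP1 against LXSN with vehicle (0.30, adjusted p = 0.0207). PGR, the progesterone receptor, rose with E2 from 0.579 ± 0.0699 to 7.82 ± 0.434 FPKM in LXSN (log2 fold change 2.48, adjusted p = 4.21e-13), by 2.77 in WT PELP1 (adjusted p = 9.76e-14) and by 2.29 in cyto PELP1 (adjusted p = 1.58e-12). With vehicle PGR was not called between lines (adjusted p = 0.805, 0.957 and 0.867). With E2 it stood at 10.1 ± 0.511 FPKM in WT PELP1 and 6.85 ± 1.18 in cyto PELP1, a log2 fold change against LXSN of 0.33 (adjusted p = 0.00981) and -0.18 (adjusted p = 0.143). Cyto PELP1 was called lower without cyto PELP1 E2 replicate 3 (-0.29, adjusted p = 0.0102).

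E2 against vehicle in LXSN gives the hormone response without introduced PELP1. HSPB8, a small heat-shock protein, rose from 57.3 ± 1.71 to 784 ± 15.8 FPKM (log2 fold change 3.75, SE 0.03, adjusted p = 4.44e-21). GREB1, a receptor cofactor, rose to 156 ± 6.53 FPKM (2.77), and the growth regulator MYC from 23.8 ± 1.77 to 132 ± 2.48 FPKM (2.42). The cytokines IL20 (4.15, to 85.4 ± 1.34 FPKM) and IL24 (3.43), the growth factor binder FGFBP2 (4.08) and the chemokine CXCL12 (3.44) had large log2 fold changes. PTGES, which makes prostaglandin E2, rose by 3.53, the adenosine receptor ADORA1 by 3.17 and the neuropeptide receptor NPY1R by 3.12. The falling genes included TP53INP1, a stress protein (-1.89, from 30.9 ± 1.45 to 7.60 ± 0.218 FPKM), the lipid receptor S1PR3 (-1.81), the membrane estrogen receptor GPER (-1.66), the pro-apoptotic BMF (-1.60) and the cyclin CCNG2 (-1.55). In total 3626 genes rose and 3405 fell at adjusted p under 0.05, of which 249 rose and 61 fell more than 2-fold. After quantile normalization the split was 3097 higher and 3946 lower, so the excess of rising genes depends on the scaling. The 3 libraries of one group lay wholly above those of the other for 63.5% of genes, where chance gives 10%.

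Among the gene lists in LXSN, the classical E2-induced genes went up, as 44 of 44 measured rose and 0 fell (camera adjusted p = 1.32e-30, adjusted p = 1.61e-05 with an estimated correlation). Their members TFF1 (2.35), MYC and HSPB8 had the smallest adjusted p with PTGES. Of the E2-repressed genes 0 of 24 measured rose and 21 fell (camera adjusted p = 1.44e-10, adjusted p = 0.00245 with an estimated correlation), with ERBB2, a growth factor receptor, at -1.08. For ribosome biogenesis 34 of 34 measured rose and 0 fell (camera adjusted p = 6.35e-25, adjusted p = 0.00245 with an estimated correlation), with NOLC1 at 1.42, DKC1 at 1.33 and DDX21 at 1.36. These 3 lists were the ones called with an estimated correlation. For G1/S and replication 34 of 35 measured rose and 0 fell (camera adjusted p = 5.96e-14, adjusted p = 0.0957 with an estimated correlation), with the licensing factor CDT1 at 1.03 and the helicase subunit MCM7 at 0.77. For glycolysis 14 of 22 measured rose and 3 fell (camera adjusted p = 0.000326, adjusted p = 0.0957 with an estimated correlation), with the glucose transporter SLC2A1 at 1.78, the lactate transporter SLC16A1 at 1.73 and LDHA at 0.53. After quantile normalization 5 glycolysis members fell. Of the 5FMC and Rix1 complex genes, whose products bind PELP1, 7 of 9 measured rose and 1 fell (camera adjusted p = 0.024, adjusted p = 0.16 with an estimated correlation), with SENP3 at 0.57 and TEX10 at 0.61. For the unfolded protein and amino-acid stress list 15 of 25 measured rose and 4 fell (camera adjusted p = 0.0118, adjusted p = 0.191 with an estimated correlation), with XBP1 at 0.91 and SLC3A2 at 1.24.

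The interferon-stimulated genes went down with E2 in LXSN, as 0 of 34 measured rose and 22 fell (camera adjusted p = 0.000138, adjusted p = 0.485 with an estimated correlation), with IRF9 at -0.64 and PARP14 at -0.54. Of the p53 targets 3 of 23 measured rose and 11 fell (camera adjusted p = 0.0168, adjusted p = 0.106 with an estimated correlation), with CCNG1 at -0.53 and BTG2 at -0.90 against AEN at 1.42. Of the basal epithelial genes 0 of 10 measured rose and 4 fell (camera adjusted p = 0.0396, adjusted p = 0.106 with an estimated correlation), with the integrin ITGB4 at -0.60. The list was not called after quantile normalization (camera adjusted p = 0.0679). For G2/M and mitosis 3 of 34 measured rose and 16 fell (camera adjusted p = 0.0396, adjusted p = 0.55 with an estimated correlation), and 10 fell without LXSN E2 replicate 1 or 2. HMMR, a spindle protein, fell (log2 fold change -0.35), while the checkpoint gene MAD2L1 rose by 0.72. The remaining lists were not called by camera, given as members that rose and fell with the camera adjusted p in brackets. They were breast cancer stem cell markers 3 and 4 of 13 (0.462), hypoxia response 5 and 8 of 17 (0.448), PELP1 and AIB1 complex genes 6 and 10 of 20 (0.303), MYC and immediate-early genes 5 and 7 of 22 (0.93) and NF-kB and inflammatory genes 3 and 2 of 12 (0.93, 2 and 1 adjusted over the list alone). Others were antigen presentation 0 and 4 of 14 (0.372, 0 and 2 adjusted over the list alone), EMT and mesenchymal genes 1 and 3 of 10 (0.462), luminal epithelial genes 7 and 9 of 20 (0.548, 7 and 11 adjusted over the list alone), progesterone receptor-associated genes 6 and 4 of 14 (0.448) and cholesterol biosynthesis 6 and 8 of 23 (0.785, 8 and 8 adjusted over the list alone). The same held for oxidative phosphorylation 5 and 4 of 30 (0.804, 5 and 2 adjusted over the list alone), apoptosis regulators 5 and 10 of 20 (0.106) and growth factor receptor signalling 4 and 7 of 18 (0.447). After quantile normalization 1 rose and 16 fell in oxidative phosphorylation. There 3 rose without LXSN vehicle replicate 1, and 2 fell without LXSN vehicle replicate 2 or 3 or LXSN E2 replicate 2 and when only the compared groups were fitted. In the NF-kB list 1 fell without LXSN vehicle replicate 1, 2 or 3 or LXSN E2 replicate 2 or 3, with no filter and after quantile normalization. The lists for other cell types and RNA quality gave fibroblast markers 0 and 1 of 4 (0.448, 0 and 0 adjusted over the list alone), leukocyte markers 0 and 0 of 1 (0.93), basal B breast line markers 1 and 1 of 9 (0.93) and replication-dependent histones 0 and 4 of 7 (0.0822). None of the 11 endothelial markers passed the filter, and none of the 13 mitochondrial transcripts is in the table. Of the breast cancer stem cell markers, CD44 rose by 0.86, while NOTCH3 (-0.74) and the integrin ITGA6 (-0.76) fell.

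E2 against vehicle in WT PELP1 asks how the response runs with introduced PELP1. IL20 rose from 0.755 ± 0.251 to 39.0 ± 1.03 FPKM (log2 fold change 4.52, SE 0.12, adjusted p = 8.61e-15). HSPB8 rose to 600.3 ± 12.3 FPKM (3.66, adjusted p = 6.52e-21), GREB1 to 147 ± 3.65 FPKM (2.94) and MYC to 127 ± 0.148 FPKM (2.67). FGFBP2 (4.14), ADORA1 (3.53), CXCL12 (3.51), the potassium channel KCNK5 (3.34), EGR3 (3.15) and the secreted OLFML3 (3.14) also rose. TP53INP1 (-1.77), GPER (-1.70), BMF (-1.66) and S1PR3 (-1.65) fell. In all 3502 genes rose and 3473 fell (252 and 54 more than 2-fold), and 63.6% of genes separated the groups completely, where chance gives 10%. After quantile normalization 3083 were higher and 3941 lower. Of the classical E2-induced genes 44 of 44 measured rose and 0 fell (camera adjusted p = 4.52e-32, adjusted p = 1.25e-05 with an estimated correlation). E2-repressed genes went down, as 0 of 24 measured rose and 19 fell (0 and 21 adjusted over the list alone, camera adjusted p = 4.15e-10, adjusted p = 0.00263 with an estimated correlation). In ribosome biogenesis 34 of 34 measured rose and 0 fell (camera adjusted p = 1.64e-26, adjusted p = 0.00263 with an estimated correlation). Among G1/S and replication genes 34 of 35 measured rose and 0 fell (camera adjusted p = 5.46e-14, adjusted p = 0.11 with an estimated correlation). Of the glycolysis genes 14 of 22 measured rose and 2 fell (camera adjusted p = 0.000541, adjusted p = 0.112 with an estimated correlation), and 4 fell after quantile normalization. Interferon-stimulated genes went down, as 0 of 34 measured rose and 24 fell (0 and 25 adjusted over the list alone, camera adjusted p = 2.9e-05, adjusted p = 0.436 with an estimated correlation). Of the 5FMC and Rix1 complex genes 6 of 9 measured rose and 1 fell (camera adjusted p = 0.0149, adjusted p = 0.143 with an estimated correlation). In the unfolded protein and amino-acid stress list 14 of 25 measured rose and 4 fell (16 and 5 adjusted over the list alone, camera adjusted p = 0.0116, adjusted p = 0.211 with an estimated correlation).

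E2 against vehicle in cyto PELP1 gives the response with the cytoplasmic form. IL20 rose from 1.41 ± 0.495 to 49.0 ± 4.81 FPKM (log2 fold change 4.39, SE 0.12, adjusted p = 1.46e-14), HSPB8 to 561 ± 7.60 FPKM (3.50), GREB1 to 134 ± 12.3 FPKM (2.91) and MYC to 113 ± 0.950 FPKM (2.05). FGFBP2 (3.46), IL24 (3.08), ADORA1 (2.95), KCNK5 (2.91) and EGR3 (2.90) rose. GPER (-1.59), TP53INP1 (-1.48), ST6GALNAC2 (-1.42), BMF (-1.36), TSC22D3 (-1.29) and CCNG2 (-1.27) fell. In all 3361 genes rose and 3309 fell (180 and 38 more than 2-fold), and 56.3% of genes separated the groups completely (chance 10%). After quantile normalization 3057 were higher and 3668 lower. Of the classical E2-induced genes 44 of 44 measured rose and 0 fell (camera adjusted p = 1.36e-32, adjusted p = 1.14e-05 with an estimated correlation). E2-repressed genes went down, as 0 of 24 measured rose and 20 fell (camera adjusted p = 6.91e-10, adjusted p = 0.0029 with an estimated correlation). In ribosome biogenesis 34 of 34 measured rose and 0 fell (camera adjusted p = 2.49e-26, adjusted p = 0.00289 with an estimated correlation). Among G1/S and replication genes 35 of 35 measured rose and 0 fell (camera adjusted p = 1.42e-16, adjusted p = 0.0677 with an estimated correlation). Of the glycolysis genes 13 of 22 measured rose and 2 fell (camera adjusted p = 0.00541, adjusted p = 0.158 with an estimated correlation). Interferon-stimulated genes went down, as 0 of 34 measured rose and 29 fell (camera adjusted p = 3.08e-08, adjusted p = 0.257 with an estimated correlation). Of the 5FMC and Rix1 complex genes 6 of 9 measured rose and 1 fell (camera adjusted p = 0.0263, adjusted p = 0.158 with an estimated correlation). In the unfolded protein and amino-acid stress list 16 of 25 measured rose and 4 fell (camera adjusted p = 0.0154, adjusted p = 0.21 with an estimated correlation). Of the p53 targets 3 of 23 measured rose and 12 fell (camera adjusted p = 0.034, adjusted p = 0.158 with an estimated correlation). The 3 lines shared 2761 genes called higher and 2364 called lower with E2.

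**Figure D2:**
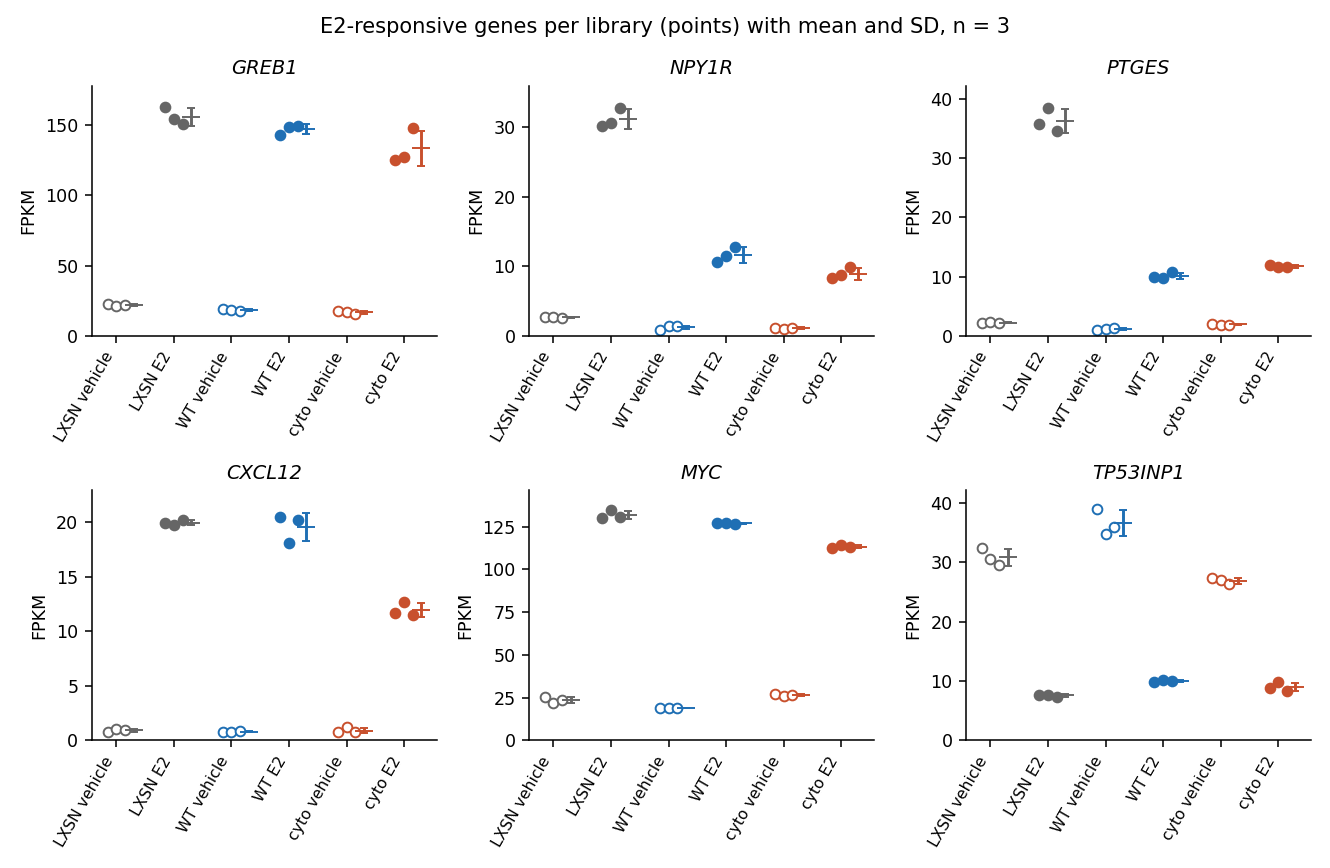
FPKM of GREB1, NPY1R, PTGES, CXCL12, MYC and TP53INP1 per library (points; open, vehicle; filled, E2) with mean and SD of 3 libraries, by cell line and treatment. PTGES with E2 averages 36.3 FPKM in LXSN, 10.2 in WT PELP1 and 11.7 in cyto PELP1.

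WT PELP1 against LXSN compares the line with introduced PELP1 and the empty-vector line. With vehicle, the ketone-body enzyme HMGCS2 stood at 6.40 ± 0.655 FPKM in WT PELP1 against 0.408 ± 0.119 in LXSN (log2 fold change 2.39, SE 0.09, adjusted p = 5.42e-12). The detoxifying enzyme UGT1A6, which shares exons with its neighbours so that reads cannot be assigned to it alone, was lower at 1.72 ± 0.286 against 13.5 ± 0.628 FPKM (-2.42, adjusted p = 2.12e-10). The secreted CRISP3 (2.27), the proline enzyme PRODH (1.97), the fatty-acid transporter CD36 (1.85), the keratin KRT81, which has near copies (1.61), DSCR8 (1.57) and the selenoprotein SEPP1 (1.45) were higher. Lower were MGST1, a glutathione transferase (-2.28), the decoy receptor TNFRSF11B (-2.13), the growth factor KITLG (-2.12, from 64.6 ± 3.69 to 14.1 ± 1.07 FPKM), the glycogen enzyme PYGL (-1.60) and TCHHL1 (-1.58). In all 1786 genes were higher and 1888 lower (35 and 34 more than 2-fold), and 44.6% of genes separated the groups completely (chance 10%).

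Of G1/S and replication genes with vehicle, 0 of 35 measured were higher and 32 were lower (0 and 33 adjusted over the list alone, camera adjusted p = 1.38e-18, adjusted p = 0.0927 with an estimated correlation), with MCM7 at -0.62, GINS2 at -0.84 and CDT1 at -0.63. For G2/M and mitosis 0 of 34 measured were higher and 33 were lower (camera adjusted p = 1.83e-21, adjusted p = 0.0767 with an estimated correlation), with the spindle factor TPX2 at -0.50 and the survivin gene BIRC5 at -0.54. For ribosome biogenesis 0 of 34 measured were higher and 21 were lower (0 and 24 adjusted over the list alone, camera adjusted p = 4.87e-07, adjusted p = 0.207 with an estimated correlation), with NOP56 at -0.28. The classical E2-induced genes were not called, with 11 higher and 15 lower (14 and 16 adjusted over the list alone, camera adjusted p = 0.821). Antigen presentation was not called, but PSMB8 (-1.17) and PSMB9 (-0.64) were lower.

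With E2, the same pair of lines differed in HMGCS2 (1.94, adjusted p = 8.38e-11), CRISP3 (1.99), PRODH (1.92), CD36 (1.61), KRT81 (1.61), DSCR8 (2.07) and RBP5 (1.30), all higher in WT PELP1. UGT1A6 (-2.16), PEG10 (-2.11), MGST1 (-2.10), KITLG (-1.81), PTGES (-1.74, 10.2 ± 0.507 against 36.3 ± 1.96 FPKM) and PSMB8 (-1.68) were lower. In all 1572 genes were higher and 1764 lower (28 and 31 more than 2-fold), and 42.8% of genes separated the groups completely (chance 10%). After quantile normalization 1631 were higher and 1610 lower. Among G1/S and replication genes 0 of 35 measured were higher and 31 were lower (0 and 34 adjusted over the list alone, camera adjusted p = 1.57e-19, adjusted p = 0.0755 with an estimated correlation). Among G2/M and mitosis genes 0 of 34 measured were higher and 30 were lower (0 and 31 adjusted over the list alone, camera adjusted p = 6.63e-19, adjusted p = 0.0755 with an estimated correlation). Ribosome biogenesis was lower, as 0 of 34 measured were higher and 10 were lower (camera adjusted p = 0.002, adjusted p = 0.399 with an estimated correlation). Of the E2-repressed genes 9 of 24 measured were higher and 3 were lower (camera adjusted p = 0.0176, adjusted p = 0.199 with an estimated correlation), with TXNIP, an inhibitor of glucose uptake, at 0.61.

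Cyto PELP1 against LXSN compares the line with the cytoplasmic form and the empty-vector line. With vehicle, the membrane protein gene EMC10 stood at 0.398 ± 0.0455 FPKM in cyto PELP1, 10.5 ± 0.666 in LXSN and 19.6 ± 0.951 in WT PELP1 (log2 fold change against LXSN -3.04, SE 0.07, adjusted p = 8.02e-15). The matrix linker HAPLN1 was at 5.18 ± 0.279 against 0.261 ± 0.0515 FPKM (2.29, adjusted p = 3.42e-12). FAM109B was at 1.98 ± 0.507 FPKM in cyto PELP1 and 0.0520 ± 0.0451 in LXSN (1.49). PRODH (1.55), KRT81 (1.49), UBE2QL1 (1.36), the water channel AQP3 (1.28) and the mucosal peptide TFF3 (1.07) were higher. UGT1A6 (-1.88), MGST1 (-1.79), KITLG (-1.69) and TCHHL1 (-1.53) were lower. In all 1510 genes were higher and 1705 lower (17 and 23 more than 2-fold), and 40.9% of genes separated the groups completely (chance 10%). FAM71E1, which overlaps EMC10, was at 0.410 ± 0.201 FPKM in cyto PELP1 and 1.16 ± 0.148 in LXSN with vehicle. Whether the low EMC10 goes with the PELP1 form or with a change particular to this line, such as an insertion or a clonal event, was not tested.

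For G1/S and replication with vehicle, 0 of 35 measured were higher and 28 were lower (0 and 29 adjusted over the list alone, camera adjusted p = 1.4e-14, adjusted p = 0.189 with an estimated correlation), with MCM7 at -0.45 and the thymidine kinase TK1 at -0.44. For G2/M and mitosis 0 of 34 measured were higher and 31 were lower (0 and 34 adjusted over the list alone, camera adjusted p = 8.71e-21, adjusted p = 0.0856 with an estimated correlation), with PLK1, a mitotic kinase, at -0.50 and TPX2 at -0.53. Of the interferon-stimulated genes 19 of 34 measured were higher and 0 were lower (24 and 0 adjusted over the list alone, camera adjusted p = 3.67e-06, adjusted p = 0.446 with an estimated correlation), with the RNA sensor IFIH1 at 0.39 and ISG15 at 0.32. The number of higher interferon-stimulated genes was 11 without LXSN vehicle replicate 1, 12 without LXSN vehicle replicate 2, 11 without cyto PELP1 vehicle replicate 2 and 12 without cyto PELP1 vehicle replicate 3. Of the antigen presentation genes 7 of 14 measured were higher and 0 were lower (8 and 0 adjusted over the list alone, camera adjusted p = 0.000347, adjusted p = 0.226 with an estimated correlation), with B2M at 0.43 and the peptide transporter TAP1 at 0.32. Of the replication-dependent histones 0 of 7 measured were higher and 4 were lower (camera adjusted p = 0.0494, adjusted p = 0.226 with an estimated correlation), with HIST1H2BK at -0.24.

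With E2, cyto PELP1 differed from LXSN in EMC10 (-2.84), HAPLN1 (2.21, adjusted p = 4.29e-12), FAM109B (1.70), KRT81 (1.59), PRODH (1.54), DSCR8 (1.49) and UBE2QL1 (1.38). PEG10 (-2.14), NPY1R (-1.69, 8.96 ± 0.866 against 31.2 ± 1.40 FPKM), UGT1A6 (-1.69), MGST1 (-1.57), PTGES (-1.55) and TCHHL1 (-1.55) were lower. In all 1514 genes were higher and 1981 lower (14 and 18 more than 2-fold), and 38.5% of genes separated the groups completely (chance 10%). After quantile normalization the split turned to 1834 higher and 1561 lower, and 2317 genes were called when only the 6 libraries of the comparison were fitted.

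With E2, 0 of 35 measured were higher and 24 were lower (0 and 27 adjusted over the list alone, camera adjusted p = 1.78e-11, adjusted p = 0.141 with an estimated correlation) in the G1/S and replication list. In the G2/M and mitosis list 0 of 34 measured were higher and 28 were lower (0 and 31 adjusted over the list alone, camera adjusted p = 3.3e-12, adjusted p = 0.141 with an estimated correlation). Of the classical E2-induced genes 6 of 44 measured were higher and 23 were lower (camera adjusted p = 7.39e-05, adjusted p = 0.0985 with an estimated correlation), with the lysosomal protease CTSD at -0.71 and the secreted STC2 at -0.89. Of the E2-repressed genes 9 of 24 measured were higher and 3 were lower (camera adjusted p = 0.00436, adjusted p = 0.141 with an estimated correlation), with the transcription factor KLF6 at 0.74. For ribosome biogenesis 0 of 34 measured were higher and 13 were lower (0 and 17 adjusted over the list alone, camera adjusted p = 0.000135, adjusted p = 0.247 with an estimated correlation), with BOP1 at -0.37, and 8 were lower and 1 higher without cyto PELP1 E2 replicate 1. Of the interferon-stimulated genes 10 of 34 measured were higher and 3 were lower (camera adjusted p = 0.0231, adjusted p = 0.594 with an estimated correlation). The number of higher interferon-stimulated genes was 6 without LXSN E2 replicate 2 and also when only the compared groups were fitted. The number lower was 1 without LXSN E2 replicate 1 and with no filter, and 0 without LXSN E2 replicate 2, without cyto PELP1 E2 replicate 3 and after quantile normalization. Of the antigen presentation genes 7 of 14 measured were higher and 0 were lower (9 and 1 adjusted over the list alone, camera adjusted p = 0.00436, adjusted p = 0.247 with an estimated correlation). The number of higher antigen presentation genes was 3 without LXSN E2 replicate 1 or 3 or cyto PELP1 E2 replicate 1 and with no filter. Of the basal epithelial genes 4 of 10 measured were higher and 0 were lower (camera adjusted p = 0.0204, adjusted p = 0.141 with an estimated correlation), with the cadherin CDH3 at 0.41. The number of higher basal genes was 2 without LXSN E2 replicate 1 and when only the compared groups were fitted, and 1 was lower without cyto PELP1 E2 replicate 1. For cholesterol biosynthesis 2 of 23 measured were higher and 11 were lower (3 and 12 adjusted over the list alone, camera adjusted p = 0.0265, adjusted p = 0.413 with an estimated correlation), with MVD at -0.44 and HMGCS1 at -0.42. The number higher was 0 without LXSN E2 replicate 1, without cyto PELP1 E2 replicate 2, with no filter and when only the compared groups were fitted, and 1 without LXSN E2 replicate 2 or cyto PELP1 E2 replicate 3. The list was not called after quantile normalization (camera adjusted p = 0.0978). Of the unfolded protein and amino-acid stress list 1 of 25 measured were higher and 7 were lower (camera adjusted p = 0.0326, adjusted p = 0.384 with an estimated correlation), with the serine enzyme PHGDH at -0.47, and the list was not called after quantile normalization (camera adjusted p = 0.0872).

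Both PELP1 lines were then compared in their differences from LXSN. PRODH, KRT81, UGT1A6, MGST1, KITLG, TCHHL1 and PYGL were among the genes that moved the same way in both. With vehicle, 853 genes were called higher in both lines, against 218 for independent lists, 969 lower in both, against 260.1, and 106 in opposite directions. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.60, where simulated groups without change against the same LXSN libraries gave 0.51. The covariance was 0.0479 against a simulated 0.0147. With E2, 795 genes were higher and 959 lower in both, against 192 and 282 for independent lists, and 85 went opposite ways (r = 0.56, simulated 0.50, covariance 0.0404 against 0.0146). Pairs sharing the LXSN line but no library gave 703 higher and 836 lower for WT PELP1 with vehicle and cyto PELP1 with E2. Independent lists would give 218 and 302, and r was 0.47. The reverse pair gave 676 and 814, against 192 and 243, with r = 0.25. In both lines and both treatments, 476 genes were higher and 566 lower than in LXSN.

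Cyto against WT PELP1 compares lines, and form goes with line. With vehicle, EMC10 differed most (log2 fold change -3.88, SE 0.07, adjusted p = 2.88e-16). PSMB8 stood at 4.98 ± 0.664 against 0.873 ± 0.220 FPKM (1.68, adjusted p = 5.35e-07), and PSMB9 differed by 1.03. Higher in cyto PELP1 were FAM109B (1.49), the complement factor CFB (1.28), the tryptophan enzyme KYNU (1.17), RTP4 (1.15) and HAPLN1 (1.02). Lower were HMGCS2 (-2.19, 0.613 ± 0.0627 against 6.40 ± 0.655 FPKM), the secreted PIP (-1.23), CRISP3 (-1.20), C1orf64 (-1.15), the crystallin CRYM (-1.05) and AMBP (-1.01). In all 1121 genes were higher and 1217 lower (11 and 11 more than 2-fold), and 36.1% of genes separated the groups completely (chance 10%). After quantile normalization 1218 were higher and 1157 lower.

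For antigen presentation with vehicle, 7 of 14 measured were higher and 0 were lower (8 and 0 adjusted over the list alone, camera adjusted p = 8.21e-06, adjusted p = 0.123 with an estimated correlation), with TAP1 at 0.44 and B2M at 0.29. For ribosome biogenesis 14 of 34 measured were higher and 0 were lower (16 and 0 adjusted over the list alone, camera adjusted p = 3.36e-07, adjusted p = 0.123 with an estimated correlation), with NOLC1 at 0.19. In the G1/S and replication list 9 of 35 measured were higher and 0 were lower (9 and 1 adjusted over the list alone, camera adjusted p = 0.0066, adjusted p = 0.535 with an estimated correlation), with MCM4 at 0.32. For oxidative phosphorylation 8 of 30 measured were higher and 0 were lower (10 and 0 adjusted over the list alone, camera adjusted p = 0.00219, adjusted p = 0.17 with an estimated correlation), with COX6C at 0.27. Of the interferon-stimulated genes 5 of 34 measured were higher and 3 were lower (6 and 4 adjusted over the list alone, camera adjusted p = 0.0255, adjusted p = 0.623 with an estimated correlation). The number higher there was 3 without WT PELP1 vehicle replicate 1, 2 without WT PELP1 vehicle replicate 2, 11 without WT PELP1 vehicle replicate 3, 2 without cyto PELP1 vehicle replicate 2, 3 without cyto PELP1 vehicle replicate 3 and 3 with no filter. Of the E2-repressed genes 2 of 24 measured were higher and 9 were lower (3 and 11 adjusted over the list alone, camera adjusted p = 0.0298, adjusted p = 0.214 with an estimated correlation). Of the luminal epithelial genes 4 of 20 measured were higher and 9 were lower (5 and 10 adjusted over the list alone, camera adjusted p = 0.0288, adjusted p = 0.225 with an estimated correlation), with the pioneer factor FOXA1 at -0.42. Of the progesterone receptor-associated genes 1 of 14 measured were higher and 3 were lower (camera adjusted p = 0.0391, adjusted p = 0.128 with an estimated correlation), with the cyclin CCND1 at -0.39. Of growth factor receptor signalling genes 3 of 18 measured were higher and 10 were lower (4 and 10 adjusted over the list alone, camera adjusted p = 0.0288, adjusted p = 0.123 with an estimated correlation), with EGFR higher at 0.48, and 1 was higher without WT PELP1 vehicle replicate 1. Of the PELP1 and AIB1 complex genes 2 of 20 measured were higher and 6 were lower (camera adjusted p = 0.0391, adjusted p = 0.123 with an estimated correlation). The number higher was 1 without WT PELP1 vehicle replicate 2 or 3, without cyto PELP1 vehicle replicate 1, 2 or 3, with no filter and with robust moderation. The list was not called after quantile normalization (camera adjusted p = 0.0551). Of the basal B breast line markers 3 of 9 measured were higher and 0 were lower (camera adjusted p = 0.0391, adjusted p = 0.123 with an estimated correlation), with CD44 at 0.64 and SERPINE1 at 0.78, and the list was not called after quantile normalization (camera adjusted p = 0.0656). Of the histones 0 of 7 measured were higher and 4 were lower (camera adjusted p = 0.0066, adjusted p = 0.123 with an estimated correlation), and 2 were lower without WT PELP1 vehicle replicate 2 or cyto PELP1 vehicle replicate 1.

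With E2, cyto PELP1 lay above WT PELP1 for PSMB8 (1.88, adjusted p = 1.82e-07), FAM109B (1.69), CFB (1.37), KYNU (1.24), HAPLN1 (1.24) and UQCRHL, which has a near copy (1.27). It lay below for EMC10 (-3.65), HMGCS2 (-1.88), C1orf64 (-1.42), AMBP (-1.18), ST3GAL5 (-1.07) and CRISP3 (-1.02). PGR was lower in cyto PELP1 (log2 fold change -0.51, adjusted p = 0.000599). In all 1007 genes were higher and 1305 lower (13 and 7 more than 2-fold), and 31.6% of genes separated the groups completely (chance 10%). After quantile normalization 1230 were higher and 1110 lower, and 1249 genes were called when only the 6 libraries of the comparison were fitted.

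Of the classical E2-induced genes with E2, 2 of 44 measured were higher and 20 were lower (3 and 29 adjusted over the list alone, camera adjusted p = 8.86e-08, adjusted p = 0.0121 with an estimated correlation), with RET, a receptor kinase, at -0.49 and XBP1 at -0.29. The number higher was 1 without WT PELP1 E2 replicate 1 or 2, without cyto PELP1 E2 replicate 1, 2 or 3, with no filter and when only the compared groups were fitted, and 0 with a pseudocount of 0.1. For antigen presentation 8 of 14 measured were higher and 0 were lower (camera adjusted p = 1.04e-05, adjusted p = 0.125 with an estimated correlation), with PSMB9 at 0.92 and TAP1 at 0.37, and 5 were higher without WT PELP1 E2 replicate 2. In the G1/S and replication list 6 of 35 measured were higher and 0 were lower (8 and 0 adjusted over the list alone, camera adjusted p = 0.000507, adjusted p = 0.351 with an estimated correlation). The number of higher G1/S genes was 2 without WT PELP1 E2 replicate 1, 11 without cyto PELP1 E2 replicate 1 and 2 without cyto PELP1 E2 replicate 3. For G2/M and mitosis 6 of 34 measured were higher and 0 were lower (camera adjusted p = 0.00209, adjusted p = 0.375 with an estimated correlation). The number of higher G2/M genes was 0 without WT PELP1 E2 replicate 1, 2 without WT PELP1 E2 replicate 2, 1 without cyto PELP1 E2 replicate 3 and 2 when only the compared groups were fitted. For oxidative phosphorylation 8 of 30 measured were higher and 0 were lower (9 and 0 adjusted over the list alone, camera adjusted p = 0.00169, adjusted p = 0.194 with an estimated correlation), with SDHA at 0.23, and 5 were higher when only the compared groups were fitted. For cholesterol biosynthesis 1 of 23 measured were higher and 8 were lower (3 and 10 adjusted over the list alone, camera adjusted p = 0.0214, adjusted p = 0.351 with an estimated correlation), with the receptor LDLR at -0.31. The number higher was 2 without WT PELP1 E2 replicate 3, 3 without cyto PELP1 E2 replicate 1 and 3 after quantile normalization, where the list was not called (camera adjusted p = 0.0739). Of the luminal epithelial genes 3 of 20 measured were higher and 9 were lower (5 and 9 adjusted over the list alone, camera adjusted p = 0.045, adjusted p = 0.287 with an estimated correlation). After quantile normalization 6 luminal epithelial genes were higher and the list was not called (camera adjusted p = 0.0917). Of the progesterone receptor-associated genes 1 of 14 measured were higher and 5 were lower (camera adjusted p = 0.0303, adjusted p = 0.134 with an estimated correlation). Of the basal B breast line markers 4 of 9 measured were higher and 0 were lower (5 and 0 adjusted over the list alone, camera adjusted p = 0.0317, adjusted p = 0.134 with an estimated correlation), with SERPINE1 at 0.91, and 2 were higher without WT PELP1 E2 replicate 1 or 2 or cyto PELP1 E2 replicate 1 or 2. The list was not called after quantile normalization (camera adjusted p = 0.0616).

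**Figure D3:**
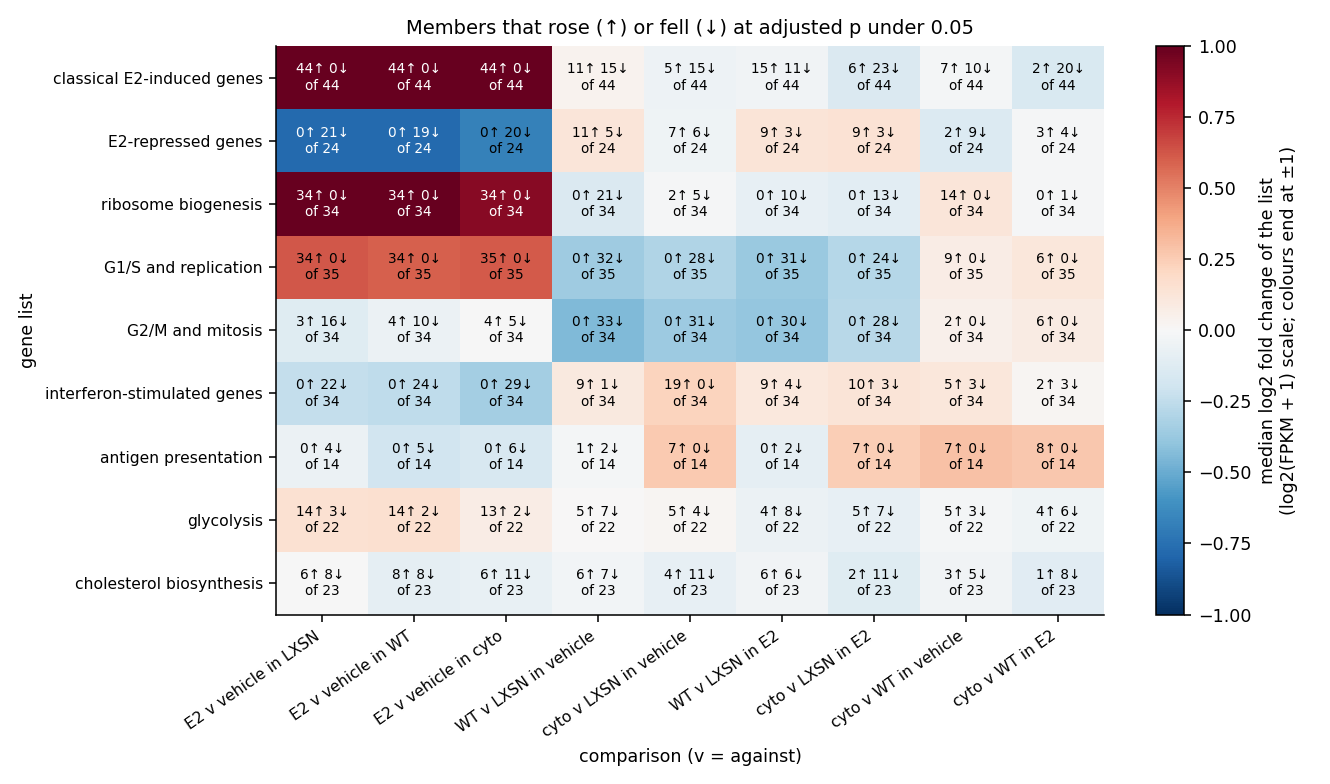
Gene lists (vertical) by comparison (horizontal), coloured by the median log2 fold change on the log2(FPKM + 1) scale, with colours ending at ±1; each cell gives the members that rose (up arrow) or fell (down arrow) of those measured. The G2/M and mitosis list fell by 28 to 33 of 34 members in the 4 comparisons of a PELP1 line with LXSN.

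The last comparisons ask whether the response to E2 differs between lines, as an interaction. FOS, an immediate-early transcription factor, rose by 1.65 in LXSN and 0.58 in WT PELP1, a difference of -1.07 (SE 0.15, adjusted p = 0.0017). PTGES rose by 3.53 in LXSN, 2.40 in WT PELP1 and 2.12 in cyto PELP1, so the differences from LXSN were -1.13 (adjusted p = 2.2e-06) and -1.41 (adjusted p = 1.42e-07). PELP1 differed from LXSN by -1.25 in WT PELP1 (adjusted p = 3.78e-07) and -1.22 in cyto PELP1 (adjusted p = 2.55e-07). The growth factor binder IGFBP5 (0.64, adjusted p = 0.00633) and C1orf21 (0.72, adjusted p = 0.00767) responded more positively in WT PELP1 than in LXSN. In cyto PELP1 the carbonic anhydrase CA12 (0.48, adjusted p = 1.7e-06), the repair gene RBBP8 (0.50) and ARHGAP18 (0.51) responded more positively than in LXSN, and IFITM10 less (-1.08, adjusted p = 0.00032). MYC rose by 2.67 in WT PELP1 and 2.05 in cyto PELP1, a difference of -0.62 (SE 0.05, adjusted p = 3.36e-05). B4GALT1, a galactosyltransferase, differed by -0.45 (adjusted p = 0.000185), and the chemokine receptor CXCR7 by 0.57 (adjusted p = 0.0115). The interactions of PGR, ESR1, NCOA3, PFKFB3 and PFKFB4 were not called, with adjusted p of 0.218, 0.551, 0.967, 0.941 and 0.935 for cyto against WT PELP1. PGR was called there without cyto PELP1 E2 replicate 3 (-0.60, adjusted p = 0.0322).

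The WT PELP1 response differed from that of LXSN for 42 genes (21 higher, 21 lower). For cyto PELP1 against LXSN the number was 64 (18 and 46), and for cyto against WT PELP1 it was 12 (4 and 8). At an unadjusted p under 0.05 the numbers were 1020, 1657 and 981. The 42 fell to 26 without WT PELP1 vehicle replicate 3. The 64 fell to 35, 33 and 39 without LXSN vehicle replicates 1, 2 and 3, to 31, 20 and 30 without LXSN E2 replicates 1, 2 and 3, and to 39, 41 and 23 without cyto PELP1 vehicle replicates 1, 2 and 3. The 12 became 5 without WT PELP1 vehicle replicate 1 or 2, 6, 7 and 6 without WT PELP1 E2 replicates 1, 2 and 3, 5 without cyto PELP1 vehicle replicate 3 or cyto PELP1 E2 replicate 1, and 22 without cyto PELP1 E2 replicate 3. After quantile normalization the 64 became 67, split 31 and 36. With a pseudocount of 0.1 they were 35, and with only the compared groups fitted 36, while the 12 were then 3. In the cyto against WT PELP1 interaction, ribosome biogenesis had a median of -0.17 (camera adjusted p = 1.55e-17, adjusted p = 0.0146 with an estimated correlation), and 1 of 34 members was lower by the interaction (12 adjusted over the list alone). That count was 2 without cyto PELP1 E2 replicate 3, with no filter and with median-ratio scaling. It was 0 without WT PELP1 vehicle replicate 1, 2 or 3, WT PELP1 E2 replicate 2 or 3, cyto PELP1 vehicle replicate 1 or 3 or cyto PELP1 E2 replicate 1, and when only the compared groups were fitted. The classical E2-induced genes had a median of -0.15 (camera adjusted p = 2.68e-09, adjusted p = 0.00662 with an estimated correlation), and 3 of 44 members were lower by the interaction (3 higher and 16 lower adjusted over the list alone). The number lower was 1 without WT PELP1 vehicle replicate 1 or 2, WT PELP1 E2 replicate 1 or 3 or cyto PELP1 E2 replicate 1, and when only the compared groups were fitted. For cyto PELP1 against LXSN, 1 of 44 responded more and 9 less (4 and 11 adjusted over the list alone, camera adjusted p = 5.04e-05, adjusted p = 0.0679 with an estimated correlation). The number that responded less was 5 without any one of LXSN vehicle replicate 1, LXSN E2 replicates 1 and 2, cyto PELP1 vehicle replicates 1 and 3 and cyto PELP1 E2 replicate 2.

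**Figure D4:**
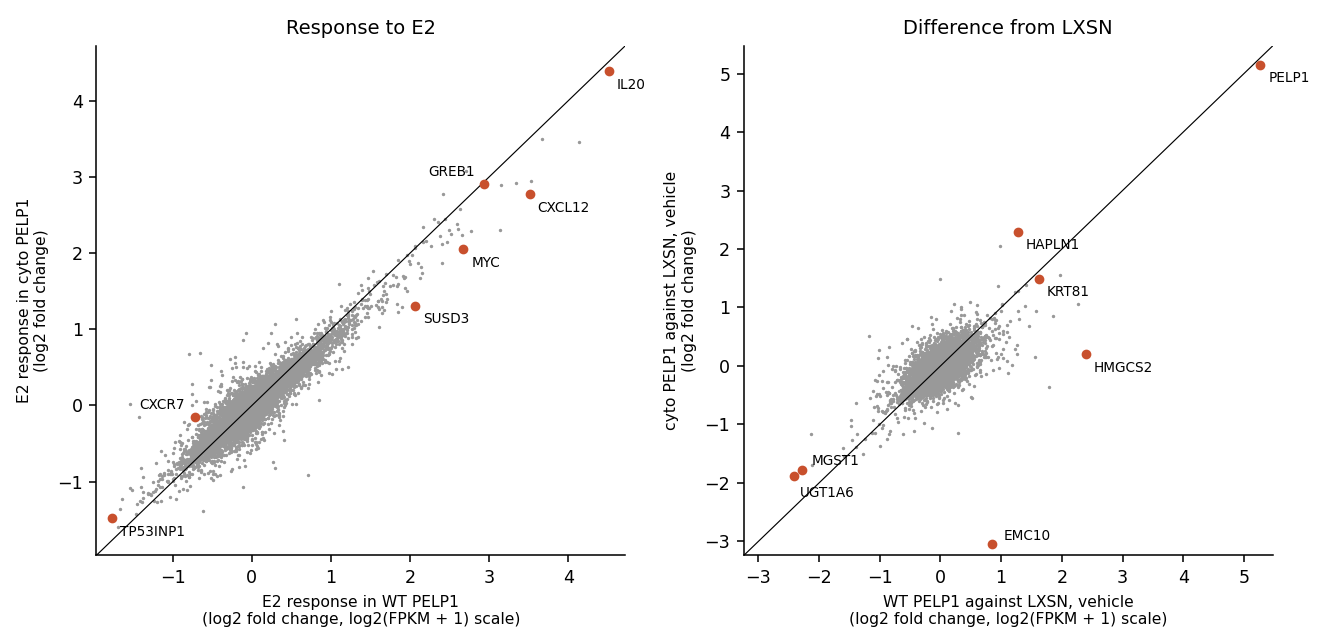
Log2 fold changes on the log2(FPKM + 1) scale, 1 point per tested gene outside the small RNA classes, with the line of equal values. Left, response to E2 in WT PELP1 (horizontal) and cyto PELP1 (vertical), with CXCL12, MYC and SUSD3 below the line; right, difference from LXSN with vehicle in both PELP1 lines, with EMC10 at -3.04 in cyto PELP1.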

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

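The tests of the shared LXSN libraries, of WT PELP1 depth and of the PELP1 pattern and the counts of list members by setting were chosen only after the result was seen. Of the rest, the comparisons and the gene lists were chosen before the data were examined. Apart from the cell-cycle lists, which differ between lines, the results here are responses to E2 that differed between cell lines by a test of the difference itself.

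The G1/S and G2/M lists were lower in both PELP1 lines than in LXSN, and the tests below used the G2/M list. None of these camera calls, made at the preset correlation, held with an estimated correlation (adjusted p between 0.0755 and 0.189 in the 4 comparisons). Chance values of the LXSN vehicle libraries, which both vehicle comparisons share, would not carry over to E2, where at least 28 of 34 G2/M members fell, and against the authors' scaling at least 25 of 34 fell in the 4 comparisons after quantile normalization. Lower depth cannot act in WT PELP1 (1.10 times the depth of LXSN). In cyto PELP1 the list median was -0.36, against -0.10 to 0.09 for 10000 random lists matched in expression but not in correlation. Growth rate and culture history go with the line and were not tested, so an effect of PELP1 and a difference between the cultures both stay open.

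The classical E2-induced genes rose less in cyto than in WT PELP1. Against compression of low values by the pseudocount, the median difference was -0.17 with a pseudocount of 0.1 and -0.15 with 1. For lower depth, 10000 lists matched as above gave -0.08 to 0.08, against the -0.15. A response smaller on balance in the responding genes could account for it: the summed response in cyto over WT PELP1 was 0.905 for lower and 0.891 for higher genes (at most 0.931 without one library), though 62.8% and 66.3% of these genes had the smaller response in cyto PELP1 and the rest did not. Whether this comes from the form of PELP1, ESR1 level or timing was not tested.

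PELP1 transcript fell with E2 in both PELP1 lines and rose in LXSN. The smaller fall was -0.59 (log2) and -0.62 after quantile normalization, which argues against the scaling. Without any one library it was -0.56 (largest adjusted p = 2.77e-06), which argues against a single deviating library. The control of the vector's promoter by E2 was not tested and stays open, as does the stability of the transcript.

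In the comparison of WT PELP1 with LXSN, PELP1 had a difference in response of -1.25, OLFML3 1.40, RFPL1 0.93, C1orf21 0.72, IGFBP5 0.64, PTGES -1.13, GEM -1.09, FOS -1.07, BMPER -1.02 and IL24 -0.73. With a pseudocount of 0.1 OLFML3 had 1.74 (adjusted p = 0.193), RFPL1 1.97 (0.394), GEM -1.09 (0.361) and BMPER -2.87 (0.0829), and IL24 turned to 0.37 (0.783). PITX1 had 0.73, with adjusted p 0.0512 (log2 0.73) at that pseudocount, 0.0712 with no filter, and 0.08 and 0.088 without LXSN vehicle replicates 2 and 3, 0.0637 and 0.0875 without LXSN E2 replicates 2 and 3, 0.0834 and 0.0846 without WT PELP1 vehicle replicates 1 and 3 and 0.0874 and 0.0716 without WT PELP1 E2 replicates 1 and 2. PLIN5 had 0.66, with adjusted p 0.191 (log2 0.70) at that pseudocount, 0.0564 with no filter, and 0.0833 and 0.0776 without LXSN vehicle replicates 1 and 3, 0.0798 and 0.0618 without LXSN E2 replicates 1 and 2, 0.0834, 0.0579 and 0.074 without WT PELP1 vehicle replicates 1, 2 and 3 and 0.0874, 0.0713 and 0.0685 without WT PELP1 E2 replicates 1, 2 and 3.

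In the comparison of cyto PELP1 with LXSN, PELP1 had a difference of -1.22, S1PR3 0.59, ARHGAP18 0.51, RBBP8 0.50, CA12 0.48, PTGES -1.41, GEM -1.12, IFITM10 -1.08, BMPER -1.01 and NPY1R -0.88. With a pseudocount of 0.1 S1PR3 had 0.54 (adjusted p = 0.0554), GEM -1.56 (0.0717), BMPER -2.89 (0.0611) and NPY1R -0.56 (0.185). PAK1 had 0.66, with adjusted p 0.0683 with only the compared groups fitted and 0.0549 without LXSN E2 replicate 1. ASAH2B, which has a near copy, had 1.2, with adjusted p 0.0717 (log2 2.53) at that pseudocount, and 0.0582 and 0.0568 without LXSN vehicle replicates 2 and 3, 0.0709 without LXSN E2 replicate 2 and 0.0572 and 0.0706 without cyto PELP1 vehicle replicates 1 and 3.

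In the comparison of cyto with WT PELP1, MYC had a difference of -0.62, B4GALT1 -0.45, CXCR7 0.57 and DEGS1 0.31. With only the compared groups fitted the adjusted p was 0.0579 for DEGS1, 0.0579 for SUSD3, 0.104 for CXCL12, 0.116 for FAM84B, 0.166 for LITAF, 0.186 for PTP4A3 and 0.121 for TIMM8B. After quantile normalization it was 0.082 for FAM84B and 0.0935 for LITAF. SUSD3 had -0.76, with adjusted p 0.0517 without cyto PELP1 vehicle replicate 3. CXCL12 had -0.74, with adjusted p 0.117 (log2 -0.84) at a pseudocount of 0.1, and 0.0652 and 0.0525 without WT PELP1 vehicle replicates 1 and 2, 0.0653 and 0.0508 without WT PELP1 E2 replicates 1 and 3 and 0.0562 without cyto PELP1 E2 replicate 1. FAM84B had 0.20, with adjusted p 0.0876, 0.0896 and 0.0805 without WT PELP1 vehicle replicates 1, 2 and 3, 0.15, 0.123 and 0.0508 without WT PELP1 E2 replicates 1, 2 and 3, 0.0812, 0.0954 and 0.103 without cyto PELP1 vehicle replicates 1, 2 and 3 and 0.0953 and 0.102 without cyto PELP1 E2 replicates 1 and 2. LITAF had 0.19, with adjusted p 0.0876 and 0.0971 without WT PELP1 vehicle replicates 1 and 2, 0.14, 0.123 and 0.0508 without WT PELP1 E2 replicates 1, 2 and 3, 0.0946, 0.0673 and 0.103 without cyto PELP1 vehicle replicates 1, 2 and 3 and 0.0953 and 0.102 without cyto PELP1 E2 replicates 1 and 2. PTP4A3 had -0.34, with adjusted p 0.0768, 0.107 and 0.106 without WT PELP1 vehicle replicates 1, 2 and 3, 0.147 and 0.0958 without WT PELP1 E2 replicates 1 and 3, 0.0946, 0.0666 and 0.103 without cyto PELP1 vehicle replicates 1, 2 and 3 and 0.0953 and 0.0515 without cyto PELP1 E2 replicates 1 and 3. TIMM8B had -0.31, with adjusted p 0.0795 and 0.0525 without WT PELP1 vehicle replicates 1 and 2, 0.0653, 0.115 and 0.0508 without WT PELP1 E2 replicates 1, 2 and 3, 0.0825 and 0.103 without cyto PELP1 vehicle replicates 2 and 3 and 0.0905 and 0.0536 without cyto PELP1 E2 replicates 1 and 2.

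Gene lists also differed in response by camera at its preset correlation, and most of these calls were lost with an estimated correlation. For WT PELP1 against LXSN the medians were 0.0667 for ribosome biogenesis and 0.0548 for G2/M and mitosis, where no member was called. With an estimated correlation neither list was called (adjusted p = 0.858 and 0.913). For cyto PELP1 against LXSN they were -0.10 for classical E2-induced genes, 0.14 for E2-repressed genes, -0.0927 for glycolysis, 0.0759 for PELP1 and AIB1 complex genes, -0.0909 for ribosome biogenesis, 0.10 for G2/M and mitosis and -0.10 for interferon-stimulated genes. None of these 7 was called with an estimated correlation (adjusted p = 0.0679, 0.0815, 0.305, 0.0679, 0.25, 0.434 and 0.66). No member was called in glycolysis, PELP1 and AIB1 complex, G2/M and interferon-stimulated genes, 1 was higher in E2-repressed genes and 1 lower in ribosome biogenesis (adjusted over the list alone 4 were higher in PELP1 and AIB1 complex genes, 6 higher and 6 lower in the last 2). In the PELP1 and AIB1 complex 1 was higher without cyto PELP1 E2 replicate 2 and after quantile normalization. The E2-repressed count was 0 without LXSN vehicle replicate 1, LXSN E2 replicate 2 or 3 or cyto PELP1 vehicle replicate 3, and 3 without cyto PELP1 E2 replicate 3. The ribosome biogenesis count was 2 without LXSN vehicle replicate 3 and 0 without LXSN vehicle replicate 1 or 2, LXSN E2 replicate 1, 2 or 3, cyto PELP1 vehicle replicate 1 or 3 or cyto PELP1 E2 replicate 3. After quantile normalization glycolysis was not called (adjusted p = 0.33). For cyto against WT PELP1 they were -0.15 for classical E2-induced genes, 0.10 for E2-repressed genes, -0.0418 for glycolysis, -0.17 for ribosome biogenesis and -0.0727 for interferon-stimulated genes. With an estimated correlation the classical genes (adjusted p = 0.00662) and ribosome biogenesis (0.0146) were called, and E2-repressed genes (0.0905), glycolysis (0.224) and interferon-stimulated genes (0.865) were not. These last 3 had no called member (4 E2-repressed and 1 glycolysis gene adjusted over the list alone), but 1 E2-repressed gene was higher without cyto PELP1 E2 replicate 3 and 1 glycolysis gene lower without cyto PELP1 vehicle replicate 2 and with a pseudocount of 0.1. After quantile normalization glycolysis was not called by camera (adjusted p = 0.587).

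For the interactions, the residuals of the model without the interaction were regrouped, with 100 groupings that include the real one. The interaction of WT PELP1 and LXSN had 42 genes and that of cyto PELP1 and LXSN 64, each reached by 1 of 100, the real one, with 1 and 2 genes as the highest other. For cyto and WT PELP1 the 12 genes were reached by 2 of 100, with 12 as the highest other, so the share was below 0.05 in all 3. For the 9 comparisons of 3 libraries with 3 the 10 splits are too few for a share under 0.05, and 1 split, the real one, reached the count in each. Real and highest other counts were 7031 and 0 for E2 in LXSN, 6975 and 0 in WT PELP1 and 6670 and 0 in cyto PELP1. With vehicle they were 3674 and 1 for WT PELP1 against LXSN, 3215 and 0 for cyto PELP1 against LXSN, and 2338 and 0 for cyto against WT PELP1. With E2 they were 3336 and 0, 3495 and 0, and 2312 and 3 in the same order.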

How the results depend on the processing

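Robust moderation and the counts of list members by setting were chosen only after the result was seen. The numbers of called genes in the 9 comparisons of group pairs stayed within 1.5 times under every alternative chosen beforehand except fitting only the compared groups, which gave 2317 for cyto PELP1 against LXSN and 1249 for cyto against WT PELP1, both with E2. In the interactions that setting gave 36 for cyto PELP1 against LXSN and 3 for cyto against WT PELP1, and a pseudocount of 0.1 gave 35 for cyto PELP1 against LXSN. With only its groups fitted, E2 in LXSN had 7020 genes against 7031. What caused these changes was not tested. Leaving out each library gave 26 to 39 for WT PELP1 against LXSN, 20 to 72 for cyto PELP1 against LXSN and 5 to 22 for cyto against WT PELP1, and these fits use fewer samples. PELP1 in cyto against WT PELP1 with vehicle passed the threshold at -0.12 with only the compared groups fitted. With the replicate block E2 in LXSN had 7066 genes, and the interactions 41, 55 and 10. The block also changed calls of named genes: ESR1 with E2 in LXSN had adjusted p 0.0599, PLIN5 0.0563 in the WT PELP1 and LXSN interaction, CAV1 0.0523 in cyto against WT PELP1 with vehicle, FAM84B 0.0637, FKBP4 0.0548 and PTP4A3 0.0638 in the cyto and WT PELP1 interaction, and NCOA3 in cyto against WT PELP1 with E2 passed at 0.0433. The block ended 1 list call, the replication-dependent histones in cyto PELP1 against LXSN with vehicle (adjusted p = 0.0545). The numbers do not pair the libraries by the rule that every pair exceed r = 0.1: 15 of 45 same-number pairs did, against 20 of 90 others, and the medians were -0.018 and -0.0175. All 3 same-number pairs exceeded it between LXSN E2 and cyto PELP1 vehicle and between LXSN E2 and WT PELP1 vehicle, and none between LXSN vehicle and LXSN E2. As a hint from the data, 10 of 18 libraries were closest to their own number.

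Of the lists called by camera, 11 for E2 in LXSN became 3 with an estimated correlation and 22 with fry. In the same order they were 8, 3 and 20 for E2 in WT PELP1, 9, 3 and 19 in cyto PELP1, 3, 0 and 12 for WT PELP1 against LXSN, 5, 0 and 16 for cyto PELP1 against LXSN and 12, 0 and 20 for cyto against WT PELP1 with vehicle. With E2 they were 4, 0 and 12, then 10, 0 and 19, then 9, 1 and 19, and in the interactions 2, 0 and 0, then 7, 0 and 5, then 5, 2 and 4. At an unadjusted p under 0.05 the camera test with an estimated correlation gave 3, 5 and 8 lists for the vehicle line comparisons, 6 and 5 for the first pair with E2, and 1 and 4 for the first interactions, and fry gave 2 for WT PELP1 against LXSN. After quantile normalization the lists called were 10 in place of 11 for E2 in LXSN, 10 in place of 12 for cyto against WT PELP1 with vehicle, 8 in place of 10 for cyto PELP1 against LXSN and 6 in place of 9 for cyto against WT PELP1 with E2. In the interaction of cyto PELP1 and LXSN 8 were called in place of 7, 6 of them shared, and in that of cyto and WT PELP1 5 in both, 4 of them shared. The lists gained there were MYC and immediate-early genes (adjusted p = 0.028) and luminal epithelial genes (0.0173) in the first and luminal epithelial genes (0.0386) in the other.

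Of 988 results of named genes under all settings, 13162 values kept direction and side of the threshold, 283 lost the call, 21 gained it and 2 reversed. IL24 in the interaction of WT PELP1 and LXSN turned to 0.37 (adjusted p = 0.783) with a pseudocount of 0.1, and KRT8 with E2 in WT PELP1 to -0.12 (adjusted p = 0.826) after quantile normalization. Neither reversed value was called, and the cause was not tested. The absolute depth is unknown, which limits what can be said of low genes, above all in cyto PELP1 (mean relative depth 0.669).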

Other observations

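The test in cyto PELP1 below was chosen only after the result was seen. Markers of fibroblasts, leukocytes and endothelium were low. Of 15 fibroblast markers 4 passed the filter, with COL1A1, a collagen, highest with a mean of 8.78 FPKM over the libraries, and of 15 leukocyte markers 1 did, CD74, at 1.75 FPKM. Of 11 endothelial markers none did, with ESAM highest at 0.579 FPKM. Of 17 basal B breast line markers 9 passed, with S100A4, a calcium binder, highest with a mean of 7.92 FPKM, and 3 of 9 with vehicle and 4 of 9 with E2 were higher in cyto than in WT PELP1. EMC10 was near 0 in cyto PELP1, at 0.544 ± 0.158 FPKM with E2 against 10.0 ± 0.518 in LXSN and 18.4 ± 0.357 in WT PELP1. FAM109B showed the opposite, at 2.38 ± 0.242 FPKM in cyto PELP1 with E2 against 0.0402 ± 0.0410 in LXSN, while its neighbour NAGA was at 8.67 ± 0.369 and 9.64 ± 0.457 FPKM.

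A hypothesis was that differences from LXSN scale with the PELP1 level, which was lower with E2. Outside small RNA genes, the variance of log2 fold changes beyond their error was taken as E2 over vehicle. It was 0.871 in WT PELP1 (0.843 to 0.903 without one library) and 1.02 in cyto PELP1 (0.981 to 1.07). Only WT PELP1 lay below 1 as needed, and with no size predicted the test cannot decide.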
